A study of Mus musculus with 7 samples.

How the data were processed

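The study measured liver mRNA by sequencing of total RNA from 7 ApoE-/- mice, 4 given saline and 3 given PX-478, with libraries made by Illumina protocols, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels number the samples without stating how the animals were housed or processed, so p-values measure the spread between these samples only.

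The authors deposited a table of whole-number read counts per gene with Entrez Gene IDs. Counting with featureCounts, testing with edgeR and the genome build mm10 are named in the submitters' processing notes, without versions, and the aligner is not given in the sources used here. The deposited counts are not normalized. Every one of the 14889 genes had a CPM above 0.5 in at least 2 of the 14 count columns, so genes of lower level had been removed before deposit. Per the file headers, the authors also give the log2 fold change of PX-478 over saline and the average log2 CPM of their edgeR test. The F statistic of that test is a score by the authors, and the deposited p-value beside it is not adjusted. Another 7 columns of per-sample averages were not used here.

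The table holds 2 count columns for each sample. Over genes with more than 20 reads in both columns together, chi-square per gene was 0.291 to 0.765 between the columns of a sample and 49.2 to 146 between libraries of a group. Both columns differed by less than the sampling noise and were counted as 1 sample, as their mean rounded to a whole number. The design fixed beforehand had assumed 1 column per sample. What distinguishes the columns is not given in the sources used here, and how the authors entered them into their test is not stated there either.

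Of the Entrez IDs, 14492 were found in a RefSeq gene table of the GRCm38.p6 assembly, which shares its coordinates with mm10. It supplied gene positions and the names of 19 symbols that a spreadsheet had turned into dates, while 212 entries had no symbol in the deposited table. The counting notes state no use of strand, so reads of overlapping and antisense genes cannot be told apart.

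Genes were filtered with filterByExpr, which left 13693, and libraries were scaled by trimmed mean of M-values (TMM). The groups were compared with edgeR's quasi-likelihood F test with robust dispersion estimates, without covariates, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F, and intervals are at 95%. Levels are TMM-scaled CPM, given as mean ± SD over 4 saline and 3 PX-478 libraries. The biological coefficient of variation was 0.325. In 1 library a count of 3 reads corresponds to 0.174 to 0.292 CPM, and these floors cover counting error only.

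A set of 38 gene lists was fixed before the data were examined, together with the tests, and 34 had at least 5 tested genes. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists. The other settings of the list test were an estimated correlation per list and fry. None of the 12 lists past the threshold kept its call with an estimated correlation or in fry's directional test. Counts "adjusted over the list alone" apply Benjamini-Hochberg within a list. Library-level measures were compared by an exact two-sided permutation test over all 35 assignments, where the smallest possible p is 0.0286, adjusted over 14 measures. Adjusted over 14 measures or 34 lists, a result at that smallest p can pass only if many others reach it too. Mean log2 CPM of a list uses a prior count of 2.

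Genes named in the text followed a rule set beforehand. It takes a fixed set of HIF, lipid, p53 and iron genes, the genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the groups, and the 5 smallest p-values of a direction with fewer than 5 such genes. From each list described it takes the 4 members with the smallest p, or 2 where the list did not pass, and it adds 5 sex-linked genes, of which Xist was not analysed here. Some genes that the rule takes are not reported here.

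The test was tried on simulated counts with the real genes, means, dispersions and library sizes. Of 100 genes changed 2-fold between PX-478 and saline the test recovered 39%, and of 100 changed 4-fold 95%, among 13227 genes tested, while 13 unchanged genes were called. With no gene changed it called 0 genes and 0 lists, and a shift of 0.5 on the log2 scale in the p53 list was called with no other list. Genes were simulated independently of each other, so the simulation cannot show how often lists of correlated genes are called without a change.

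Alternatives were other scalings, count filters, thresholds and tools, a replicate block, leaving out each library, and other list tests. Those chosen after seeing the data were each column alone, the sum of both, all 14 columns as libraries, leaving out mitochondrially encoded genes, leaving out saline 3 with PX-478 2, and the permutation test of list means. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.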

Results

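Liver RNA was sequenced from ApoE-/- mice on the C57BL/6 background that had eaten a Western diet for 3 months. The labels give the age of every mouse as 4 months. ApoE-/- mice lack apolipoprotein E, the ligand through which remnant lipoproteins are cleared, and develop high plasma cholesterol and atherosclerosis. During the diet 4 mice received saline and 3 received PX-478 at 40 mg/kg by intraperitoneal injection, on a schedule that the labels call bi-weekly. PX-478 is the N-oxide of melphalan, an alkylating drug, and is used as an inhibitor of HIF-1α, the oxygen-regulated transcription factor. The comparison asks which liver transcripts differ between mice given the inhibitor and mice given saline. Each library held between 10285776 and 17257304 counted reads over 14889 genes, of which 13693 passed the count filter and were tested.

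The clearest difference between the groups was the loss of Cfd (Entrez Gene 11537), which encodes complement factor D, also called adipsin, a serine protease of the alternative complement pathway. Cfd lies on chromosome 10 from 79890853 to 79892655 in mm10. Its level was 25.7 ± 11.3 CPM (TMM-scaled counts relative to library size, mean ± SD, n = 4) in saline livers and 0.432 ± 0.281 CPM (SD, n = 3) in PX-478 livers, 59.5-fold lower. In read counts, the saline libraries held 201 to 466 Cfd reads and the PX-478 libraries 4 to 10. The log2 fold change was -5.89 (SE 0.50, 95% interval -6.99 to -4.80, adjusted p = 0.000662 in edgeR's quasi-likelihood test). Cfd was the only gene past the threshold among all genes tested, and no gene was higher in PX-478 at that threshold. With limma-voom the log2 fold change of Cfd was -5.85 and its adjusted p 0.257, so that tool called 0 genes, while DESeq2 called 46 genes higher and 37 lower. Leaving out saline replicate 4, PX-478 replicate 2 or PX-478 replicate 3 gave 4, 4 and 2 genes higher, and the last of these gave 3 genes lower. Without PX-478 replicate 2 the log2 fold change of Cfd was -6.53.

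At an unadjusted p under 0.05, 477 genes were higher and 477 lower in PX-478, where 684.65 in all are expected by chance. The 5 smallest p-values among genes with higher values in PX-478 belonged to Ngef, Carmil1, Tk1, Cep152 and an entry given without a symbol, Entrez Gene 100504526. Ngef, a guanine nucleotide exchange factor, stood at 59.1 ± 8.82 CPM in saline and 153 ± 30.5 CPM in PX-478, with a log2 fold change of 1.37 (SE 0.20, adjusted p = 0.0837). Tk1, the thymidine kinase of dividing cells, stood at 17.4 ± 6.81 and 91.6 ± 38.3 CPM (log2 fold change 2.40, adjusted p = 0.108). Carmil1 had a log2 fold change of 1.58, the centrosome gene Cep152 of 1.74 and the entry without a symbol of 1.67. After Cfd, the smallest p-values among genes with lower values belonged to Fitm1 at -1.39, Serpina12 at -1.61, Chpt1 at -0.93 and Leap2 at -1.29. Fitm1 takes part in lipid droplet formation, Serpina12 encodes the adipokine vaspin, Chpt1 makes phosphatidylcholine and Leap2 encodes a liver-secreted antagonist of the ghrelin receptor. None of these 8 named genes after Cfd passed in the edgeR test, and all 8 did so in DESeq2. Without PX-478 replicate 2, whose share of mitochondrially encoded reads was 21.4% against 26.6% to 35.7% in the other libraries, Ngef, Carmil1 and Tk1 passed, with adjusted p of 0.0433, 0.0320 and 0.0320.

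Neither the list of HIF-1 target genes nor that of HIF pathway components passed its test. The transcript of the drug target differed by less than the spread between libraries. Only RNA was measured, so that transcript does not show whether HIF-1α protein was lowered. Hif1a itself stood at 12.7 ± 1.05 CPM in saline and 12.2 ± 1.12 CPM in PX-478 (log2 fold change -0.06, SE 0.21, 95% interval -0.51 to 0.40). Epas1, which encodes HIF-2α, had a log2 fold change of 0.21 (SE 0.23) and Arnt, the shared dimer partner, one of 0.45 (SE 0.23, adjusted p = 0.737). Hif3a had 0 to 26 reads per library and fell below the count filter. Of 36 HIF-1 target genes tested, 18 were higher and 18 lower, with a median log2 fold change of 0.01 (adjusted p = 0.815 in limma's camera). The angiogenic factor Vegfa had a log2 fold change of 0.33 (SE 0.21), the glycolytic gene Pgk1 of -0.05 (SE 0.22) and Ldha, lactate dehydrogenase A, of -0.48 (SE 0.26). Pdk1, the kinase that limits pyruvate entry into the mitochondrion, had the smallest p of the list, at 24.8 ± 6.84 CPM in saline and 46.1 ± 10.5 CPM in PX-478, and missed the threshold even when adjusted over the list alone (adjusted p = 0.0935). Pfkl followed at a log2 fold change of 0.43. Of the 8 HIF pathway components, 4 were higher and 4 lower (adjusted p = 0.692).

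The list of HIF-2 and iron genes did not move in a common direction, with 6 of 18 tested members higher and 12 lower (adjusted p = 0.898 in camera). In fry's mixed test, which counts changes in either direction, its adjusted p was 0.0217. The p53 targets (adjusted p = 0.00245) and the macrophage markers (adjusted p = 0.0217), described below, also passed that mixed test, and no other list did. Within the list of HIF-2 and iron genes, hepcidin transcripts were higher in PX-478 when adjusted over the list alone. Hamp, which encodes hepcidin, the hormone that blocks iron export, stood at 1038 ± 482 CPM in saline and 2652 ± 931 CPM in PX-478 (log2 fold change 1.35, adjusted p = 0.0203 over the list alone). Its neighbour Hamp2 stood at 73.2 ± 14.9 and 160.3 ± 64.7 CPM (adjusted p = 0.0138 over the list alone). These neighbours are close copies of each other, so their split of reads is uncertain. Together, 3 members were higher and 1 lower when adjusted over the list alone, and 0 when adjusted over all genes. The other members, named after their values were seen, were Id1, a target of the BMP signal that drives hepcidin, at a log2 fold change of 1.04 (SE 0.32), and Fth1, ferritin heavy chain, at -0.61 (SE 0.19).

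Targets of p53, the transcription factor that responds to DNA damage, rose as a list in PX-478 livers. Of 27 tested, 22 were higher and 5 lower, with a median log2 fold change of 0.46 (adjusted p = 3.54e-07 in camera with a preset correlation, adjusted p = 0.117 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 3.90 ± 0.641 CPM in saline and 11.1 ± 2.44 CPM in PX-478 (log2 fold change 1.51, SE 0.28, adjusted p = 0.139 over all genes). Psrc1, a spindle protein, stood at 0.316 ± 0.179 and 4.06 ± 3.05 CPM. Eda2r, of the TNF receptor family, stood at 0.324 ± 0.530 and 4.16 ± 1.52 CPM, with 0 reads in 2 of the saline libraries. Without PX-478 replicate 2 the log2 fold change of Psrc1 went from 3.62 to 2.865, and without saline replicate 1 that of Eda2r went from 3.60 to 5.75. These 3 genes were higher when adjusted over the list alone (adjusted p = 0.00206, 0.00206 and 0.0249), and 0 of the 27 were when adjusted over all genes. Phlda3 had a log2 fold change of 1.65 (SE 0.53), and Mdm2, which encodes the ubiquitin ligase that degrades p53, one of 0.47 (SE 0.17). The mean log2 CPM of the list lay between 2.58 and 2.99 in the saline libraries and between 3.22 and 3.56 in the PX-478 libraries (exact permutation p = 0.0286, two-sided, the smallest that 35 assignments allow, and 0.486 adjusted over 34 lists). After that adjustment a list can pass only if many lists reach the smallest p together. The adjusted value therefore decides little, here and for the lists below.

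Cell cycle genes rose as a list as well. Of 30 tested, 28 were higher and 2 lower, with a median log2 fold change of 0.75 (adjusted p = 3.54e-07, adjusted p = 0.255 with an estimated correlation). Mki67, the proliferation marker Ki-67, stood at 5.07 ± 0.410 CPM in saline and 9.36 ± 2.17 CPM in PX-478. The replication licensing gene Mcm5 had a log2 fold change of 2.02 (SE 0.67), Ccnd1, cyclin D1, of 1.02 (SE 0.36) and the mitotic kinase gene Cdk1 of 1.41 (SE 0.56). The mean log2 CPM of the list lay between 0.54 and 0.92 in saline and between 1.27 and 1.83 in PX-478 (exact permutation p = 0.0286, and 0.486 adjusted over 34 lists). None of the 30 passed alone, whether adjusted over all genes or over the list alone. Mcm5 and Cdk1 lay below 3 CPM in both groups, and Ccnd1 went to 0.34 without PX-478 replicate 2.

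Circadian clock genes rose as a list, with 12 of 18 tested higher and 6 lower and a median log2 fold change of 0.60 (adjusted p = 5.76e-06, adjusted p = 0.255 with an estimated correlation). Tef and Dbp, rhythmic transcription factors of the PAR bZIP family, stood at 228 ± 48.3 and 62.3 ± 14.4 CPM in saline and at 522 ± 109 and 128 ± 32.3 CPM in PX-478. Clock, which encodes the partner of BMAL1 in the positive arm of the clock, was lower, at 10.3 ± 1.49 CPM in saline and 4.67 ± 1.33 CPM in PX-478 (log2 fold change -1.14, SE 0.29). When adjusted over the list alone, 5 members were higher and 1 lower, and 0 were when adjusted over all genes. Among those higher were also Per3 at 1.67 (SE 0.39) and Nr1d2 at 0.47 (SE 0.17), named after their values were seen. The saline libraries themselves differed, with mean log2 CPM of the list from 4.32 to 5.12 against 5.16 to 5.40 in PX-478 (exact permutation p = 0.0571, two-sided, and 0.486 adjusted over 34 lists).

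**Figure D1:**
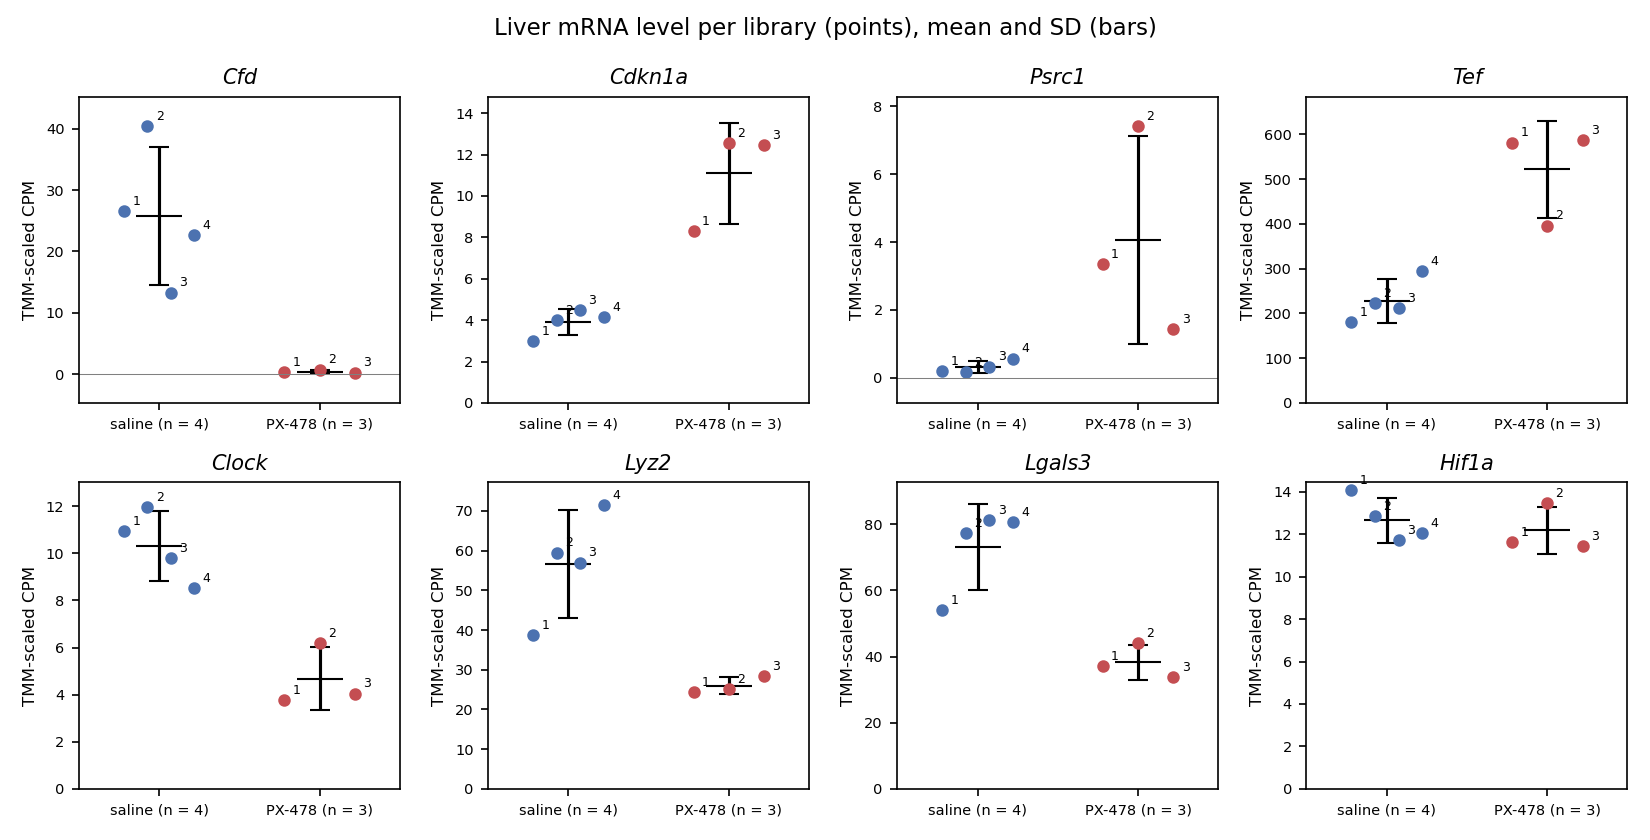
TMM-scaled CPM (vertical axes, from 0) of 8 genes in each liver library, grouped by treatment. Points are libraries with their replicate numbers, and bars show the mean and SD of 4 saline and 3 PX-478 libraries. Cfd lies at 25.7 CPM on average in saline and 0.432 CPM in PX-478, and the libraries of the groups overlap for Hif1a.

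Kupffer cell and macrophage markers fell as a list. Of 28 tested, 24 were lower and 4 higher in PX-478, with a median log2 fold change of -0.41 (adjusted p = 6.63e-07, adjusted p = 0.434 with an estimated correlation). Lyz2, which encodes lysozyme, stood at 56.6 ± 13.6 CPM in saline and 26.0 ± 2.18 CPM in PX-478. Lgals3, galectin-3, stood at 73.2 ± 13 and 38.2 ± 5.29 CPM, the lysosomal marker Cd68 at 26.1 ± 3.55 and 13.8 ± 1.02 CPM, and the complement receptor gene Vsig4 at 14.8 ± 3.80 and 7.70 ± 1.72 CPM. When adjusted over the list alone, 5 members were lower, and 0 were when adjusted over all genes. The last of these, named after its values were seen, was Gpnmb, a gene of lipid-laden macrophages, at a log2 fold change of -2.12 (SE 0.61), or -2.765 without PX-478 replicate 2. The mean log2 CPM of the list lay between 3.37 and 4.03 in saline and between 3.16 and 3.31 in PX-478 (exact permutation p = 0.0571, two-sided, and 0.486 adjusted over 34 lists).

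The acute phase list and the list of cytokine, chemokine and NF-kB target genes also passed as lower at the preset correlation, but both calls depended on which libraries were kept. Of 25 acute phase genes, 23 were lower and 2 higher (median log2 fold change -0.51, adjusted p = 5.76e-06, adjusted p = 0.733 with an estimated correlation). Saa3 and Apcs, which encode a serum amyloid A and serum amyloid P, had log2 fold changes of -1.07 (SE 0.27) and -1.10 (SE 0.29), while Hamp, an iron hormone gene placed in this list for its response to interleukin-6, went the other way. When adjusted over the list alone, Saa3 and Apcs were lower and Hamp higher. Lcn2, which encodes the iron-siderophore binding protein lipocalin-2, had a log2 fold change of -1.38 (SE 0.49). Of 24 cytokine, chemokine and NF-kB target genes, 19 were lower (median -0.28, adjusted p = 0.0168, adjusted p = 0.434 with an estimated correlation). Ccl3 had a log2 fold change of -1.92 (SE 0.78), Tnfaip3 of -0.90, Ccl2 of -0.88 and Cxcl1 of -1.09, and none passed alone. Without PX-478 replicate 1 that of Ccl3 was -2.945. The list means of both overlapped between the groups (exact permutation p = 0.314 for the acute phase and 0.0857 for the cytokine list). The acute phase call was lost without saline replicate 4 (adjusted p = 0.0571) and in the fit with replicate blocks (adjusted p = 0.0626). The cytokine call was lost without saline replicate 3, saline replicate 4 or PX-478 replicate 3 (adjusted p = 0.103, 0.0560 and 0.102), with saline 3 and PX-478 2 both left out (adjusted p = 0.0631) and in the fit with replicate blocks (adjusted p = 0.0515).

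Male-biased liver genes fell as a list, with 16 of 17 tested lower (median log2 fold change -0.59, adjusted p = 3.54e-07, adjusted p = 0.434 with an estimated correlation). Elovl3, an elongase of very long chain fatty acids whose hepatic expression depends on androgen and on time of day, stood at 129 ± 109 CPM in saline and 18.0 ± 8.21 CPM in PX-478, and its log2 fold change went from -2.84 to -2.09 without saline replicate 1. Cyp2u1 had a log2 fold change of -1.20 (SE 0.48), Cyp4a12a of -1.09 (SE 0.44) and the pheromone carrier gene Mup20 of -0.89 (SE 0.44). That of Cyp4a12a was -1.74 without PX-478 replicate 2. None passed when adjusted over the list alone. Cyp4a12a and Mup20 belong to families of near-identical genes, so their counts are uncertain. Of 18 female-biased genes fixed beforehand only 6 could be tested, of which 5 were higher (median 1.04, adjusted p = 0.00570, adjusted p = 0.434 with an estimated correlation). Cyp2a4 and Acot3 also belong to other lists, and without such shared genes this list was too small to test. Fmo2 stood at 3.84 ± 1.45 CPM in saline and 7.84 ± 0.706 CPM in PX-478 and Cyp2a4, which has a close copy in Cyp2a5, at 36.8 ± 26.6 and 160.2 ± 65.6 CPM. Both were higher when adjusted over the list alone. Ppp1r3g and Acot3 had log2 fold changes of 1.53 (SE 0.76) and 1.06 (SE 1.49), and that of Acot3 turned to -0.089 without PX-478 replicate 1 and was 2.32 without saline replicate 2. The groups overlapped in the means of both lists. For male-biased genes they ran from 7.46 to 8.53 in saline and from 6.73 to 7.84 in PX-478 (exact permutation p = 0.114), and for female-biased genes from 0.41 to 2.37 and from 2.00 to 2.79 (exact permutation p = 0.229). The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y each had at least 84 reads in all 7 libraries, so the samples came from male mice.

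**Figure D2:**
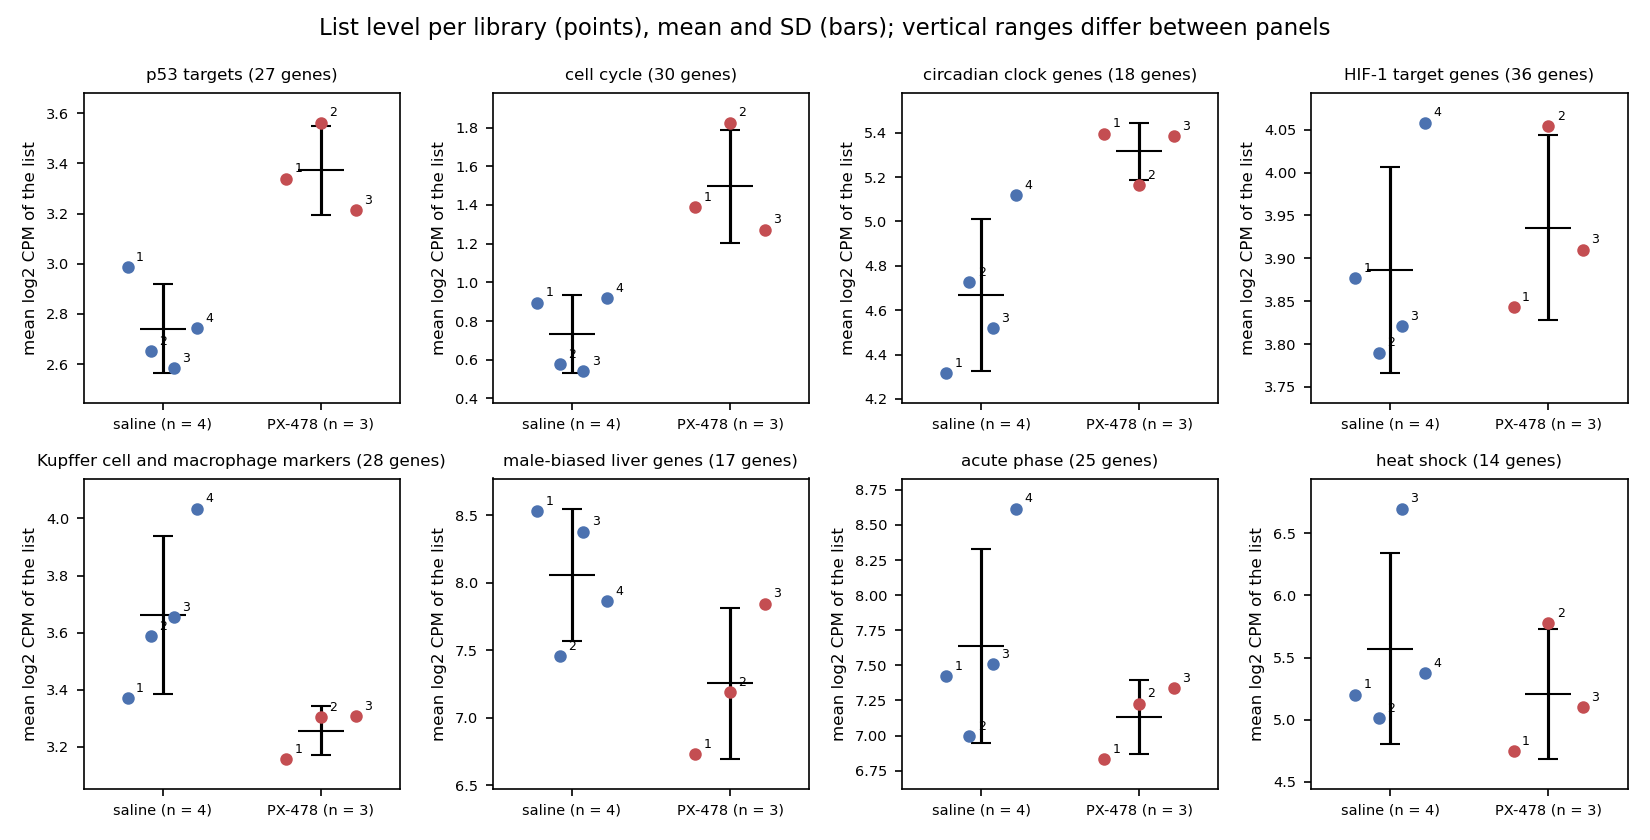
Mean log2 CPM over the tested members of 8 gene lists (vertical axes, whose ranges differ) in each library, grouped by treatment. Points are libraries with their replicate numbers, and bars show the mean and SD of 4 saline and 3 PX-478 libraries. The p53 list lies at 3.22 or above in PX-478 and at 2.99 or below in saline, and saline replicate 3 lies at 6.70 for the heat shock list.

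Subunits of oxidative phosphorylation encoded in the nucleus fell slightly as a list, with 26 of 31 lower and a median log2 fold change of -0.24 (adjusted p = 0.000897, adjusted p = 0.790 with an estimated correlation). The complex I genes Ndufb3 and Ndufb8 had log2 fold changes of -0.71 (SE 0.20) and -0.55 (SE 0.18), and the complex III genes Uqcrb and Uqcrc2 of -0.50 and -0.43. Its means overlapped between the groups (exact permutation p = 0.229). The call was lost without PX-478 replicate 1 (adjusted p = 0.137) and with saline 3 and PX-478 2 both left out (adjusted p = 0.0838). Mitochondrially encoded genes took 28.7% ± 1.88 of the counts in saline and 29.6% ± 7.34 in PX-478, and their list did not pass (adjusted p = 0.299). Pericentral hepatocyte genes fell as a list, with 11 of 14 lower (median -0.23, adjusted p = 0.00786, adjusted p = 0.733 with an estimated correlation). Oat, ornithine aminotransferase, stood at 549 ± 120 CPM in saline and 264 ± 44.1 CPM in PX-478, and Lect2, a secreted hepatokine gene, at 108 ± 2.18 and 60.1 ± 19.9 CPM. Both were lower when adjusted over the list alone, while Rhbg and Glul, glutamine synthetase, had log2 fold changes of -0.63 (SE 0.45) and -0.39 (SE 0.29), and that of Rhbg was -1.425 without PX-478 replicate 3. The pericentral call was lost without saline replicate 1, saline replicate 2 or PX-478 replicate 2 (adjusted p = 0.05305, 0.0510 and 0.415), and with saline 3 and PX-478 2 both left out (adjusted p = 0.132). The means of this list overlapped too (exact permutation p = 0.257).

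Genes of the unfolded protein response and of heat shock had lower means in PX-478, and both lists moved with a single saline library. Of 23 unfolded protein and integrated stress response genes 19 were lower (median -0.37, adjusted p = 0.0231, adjusted p = 0.790 with an estimated correlation), and of 14 heat shock genes 13 were (median -0.45, adjusted p = 0.0268, adjusted p = 0.790 with an estimated correlation). Saline replicate 3 stood apart on the first principal component, at 84.3 where the other libraries lay between -31.6 and 0.595, and its mean log2 CPM of the heat shock list was 6.70 against 5.01 to 5.37 in the other saline libraries. Without that library the adjusted p was 0.872 for the unfolded protein list and 0.835 for the heat shock list, and the direction of the heat shock list turned. The unfolded protein call was also lost without PX-478 replicate 3 (adjusted p = 0.518), and the heat shock call without PX-478 replicate 1 or 3 (adjusted p = 0.303 and 0.102). With saline 3 and PX-478 2 both left out the adjusted p of these lists was 0.774 and 0.102, with all 14 columns as separate libraries 0.0779 and 0.0885, and with replicate blocks the unfolded protein list had an adjusted p of 0.0534. The means of both lists overlapped between the groups (exact permutation p = 0.457 and 0.600). The chaperone genes Calr, Pdia3, Manf and Sdf2l1 had log2 fold changes of -0.83, -0.62, -0.82 and -1.22, and Hspe1, Dnaja1, Bag3 and Hspa8 of -0.44, -0.56, -0.69 and -0.45. Without saline replicate 3, Sdf2l1 went to -0.49 and Bag3 to -0.054.

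Lists of lipid and bile acid metabolism did not pass. Of 25 cholesterol synthesis genes, 17 were higher and 8 lower (adjusted p = 0.0669). Fdft1, squalene synthase, stood at 25.5 ± 2.57 CPM in saline and 52.7 ± 15.5 CPM in PX-478 and was the 1 member higher when adjusted over the list alone (adjusted p = 0.00785). For fatty acid oxidation and PPAR-alpha targets the adjusted p was 0.242, with Ehhadh at 0.66 (SE 0.17) and Cyp4a31 at 1.05 (SE 0.35). Among the genes followed whatever their result, Ppara had a log2 fold change of 0.15 (SE 0.28) and Cpt1a one of -0.11 (SE 0.28). For fatty acid and triglyceride synthesis the adjusted p was 0.898, with Fasn, fatty acid synthase, at 0.23 (SE 0.29), Pklr at -0.72 (SE 0.22) and Acss2 at 1.00 (SE 0.32). For bile acid synthesis and transport it was 0.780, with the rate-limiting Cyp7a1 at 0.25 (SE 0.41), Hsd3b7 at -0.65 (SE 0.19) and Cyp27a1 at 0.88 (SE 0.30). For lipoproteins and lipid uptake it was 0.0961, with Pltp at -0.80 (SE 0.23) and the fatty acid transporter gene Cd36 at -0.96 (SE 0.30). Apoe transcripts were counted in every library, at 130 to 284 CPM in saline and 144 to 351 CPM in PX-478 (log2 fold change 0.21, SE 0.35). All 7 mice carried the knockout, so these levels have no intact control and do not check the genotype.

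Markers of other cell types gave no list past the threshold. The adjusted p was 0.0668 for hepatocyte markers, 0.0744 for endothelial markers, 0.390 for T, B and NK cell markers, 0.786 for stellate cell and fibrosis genes, 0.815 for cholangiocyte markers and 0.586 for red blood cell markers. The endothelial receptor gene Kdr had a log2 fold change of 0.98 (SE 0.36) and Oit3 one of 0.57 (SE 0.26). Of the adipose markers 4 were tested, of which Cfd was lower and the other 3 had higher values. Total counts, detected genes and the share of counts in the 10 most abundant genes differed by less than the threshold of the exact permutation test (adjusted p = 0.892 for each).

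The authors' deposited table gives fold changes close to these and smaller p-values. An unadjusted p under 0.05 is given for 3861 of 14889 genes in the authors' deposited table, and Benjamini-Hochberg adjustment of those p-values leaves 1402 genes, 681 higher and 721 lower. The log2 fold change of Cfd is -5.93 in the authors' deposited table, with an unadjusted p of 2.88e-11, and that of Ngef is 1.37 with 3.93e-09. Entering both count columns of each sample as separate libraries gave 643 genes higher and 717 lower with the filter and test used here. A separate fit of these columns, without the count filter or robust estimates, gave F statistics that ranked as those in the authors' deposited table across genes (Spearman 1.00, median ratio 0.997). Over the F statistics of the 7-library fit used here, the authors' had a median ratio of 2.55. The deposited p-values thus match a test in which both columns of a sample count as separate libraries. Both columns of a sample differed by less than the sampling noise, so each pair was counted as 1 sample here.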

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

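The tests of more macrophages, of more T, B and NK cells and of adipose tissue were chosen after their results were seen, as were the 6 lists followed across divisions of the libraries, taken for their small p. The other tests were chosen before. Within the saline group, 138 measures were examined for a library far from the other 3, and 5 were found where chance gives about 1 in 20. Ppara was low in saline 3 (log2 CPM 6.41 against 7.39 to 7.52, gap 0.887 of the range), and so was Kdr (1.89 against 3.21 to 3.25, gap 0.967). Lgals3 was low in saline 1 (5.76 against 6.27 to 6.35, gap 0.877), and the mean of the cholesterol synthesis list was high there (4.61 against 4.18 to 4.22, gap 0.902). The total count of saline 2 was low (10962670 reads, gap 0.914).

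Across the 35 ways of dividing the 7 libraries into 4 and 3, 4 gave at least the 1 gene called between PX-478 and saline, and the highest other gave 6, so chance cannot be excluded for the number of genes called. For the number of lists called, 16 of the 35 gave at least the 12 of the real division, and the highest other gave 19. Many divisions thus call many lists at the preset correlation of 0.01. Estimated correlations of the 12 lists ran from 0.0166 for p53 targets to 0.716 for heat shock, all above that preset. Simulated counts of independent genes without a change gave 0 list calls at the same preset. List p-values at the preset can thus be too small, though the cause of the many calls was not tested directly. For the p53 list the real division alone gave so small a p (1 of 35, camera p = 2.87e-08 against 1.16e-07 as the smallest other in this permutation of the labels), and so it did for the cell cycle list (1 of 35, 3.13e-08 against 6.31e-07). A count of 1 of 35 is the lowest possible. The permutation test of list means, adjusted over all 34 lists, gave p = 0.486 for both. Since 35 assignments allow no p below 0.0286, that adjusted test can pass a list only if many lists reach it together. It therefore cannot decide. With lists chosen for their small p, chance is not excluded for either. Nor can it be excluded for the clock list (2 of 35, 8.99e-07 against 1.77e-11), the macrophage markers (3 of 35, 7.80e-08 against 1.24e-11), the male-biased genes (6 of 35, 2.77e-08 against 1.99e-20) or the acute phase genes (15 of 35, 1.02e-06 against 9.58e-17).

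The rise of p53 targets was weighed against a single library, depth and more immune cells. A single library is argued against, as the list mean was 3.22 to 3.56 in PX-478 libraries and 2.58 to 2.99 in saline libraries. The highest adjusted p over the 7 fits that leave out a library was 0.000679. That camera setting also calls many lists under other divisions of the libraries, so these fits decide little. Depth is argued against too, since the lowest and highest totals (10285776 and 17257304 reads) were both of PX-478 libraries. With every library thinned to the smallest total the adjusted p was 7.45e-07 in that same camera setting. More macrophages are argued against, as their markers had a median log2 fold change of -0.41 and a lower mean in each PX-478 library than in each saline library. More T, B and NK cells cannot be told apart from other causes, since their markers (median -0.39) went both ways, most of them near the floor. Chance and the treatment itself stay open, and the treatment was not tested apart from other differences between the groups.

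The fall of Cfd, an abundant transcript of fat cells, was weighed against adipose tissue attached to the saline samples. The other adipose genes that could be tested (Car3, Lipe, Adrb3 and Fabp4) had a median log2 fold change of 0.20 (SD 0.45) where Cfd had -5.89. This argues against an amount of fat large enough to move these genes. They were also counted in PX-478 livers, at 9.43 to 59.2 CPM on average, so a smaller addition from fat could be hidden. Adipoq and Plin1, adipose markers fixed beforehand, are absent from the deposited table, which holds genes above 0.5 CPM in at least 2 columns. A smaller amount of fat and the treatment itself stay open, and the treatment was not tested apart from other differences between the groups.

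The higher clock list was weighed against a single library and against a different time of collection. The highest adjusted p over the fits that leave out a library was 0.00306, in a camera setting that also calls many lists under other divisions. Those fits therefore decide little. The list mean was 5.16 to 5.40 in PX-478 libraries and 4.32 to 5.12 in saline libraries, which argues against a single library. If the PX-478 livers were at another phase, genes of the opposite phase would lie lower, and the 4 that could be tested (Arntl, Clock, Nfil3 and Cry1) had a mean log2 fold change of -0.76 (SD 0.66) against 0.94 for 9 genes of the Dbp phase. The level of these 4 did not separate the groups (exact permutation p = 0.143). Npas2, also of the opposite phase, had 3 to 68 reads in saline libraries and 0 in each PX-478 library, below the count filter. Of the 9 genes, 7 were higher and 2 lower. Their mean log2 CPM differed within saline, from 5.02 in saline 1 to 6.29 in saline 4, against 6.54 to 6.93 in PX-478 (exact permutation p = 0.0571). A shift in phase and another cause cannot be told apart. Times of collection are not given in the labels, and even a shift could come from the hour of collection or from the treatment.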

How the results depend on the processing

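Calls on single genes depended on the tool and calls on lists on the setting of the list test. Alternatives chosen after seeing the data are named in the processing summary. The 0 genes higher and 1 lower became 46 and 37 with DESeq2 and 0 and 0 with limma-voom, with or without sample weights, where the adjusted p of Cfd was 0.138 and 0.257 (range over all alternatives 2.26e-27 to 0.257, log2 fold change -6.75 to -5.59). They became 1 higher at an adjusted p under 0.1, 643 and 717 with all 14 columns as separate libraries, where the columns of a sample count as replicates, and 9 and 6 with saline 3 and PX-478 2 left out, which also ended the calls of the cytokine, oxidative phosphorylation, pericentral, unfolded protein and heat shock lists. Leaving out each library in turn gave 0 to 4 genes higher and 1 to 3 lower, and 4 to 8 lists higher (8 without PX-478 3) and 5 to 12 lower (5 without saline 3, 12 without PX-478 2). The 4 lists higher and 8 lower became 0 and 0 with an estimated correlation and 0 and 0 in fry's directional test. For the p53 list the estimate, 0.0166, lay near the preset 0.01, yet its camera p went from 2.87e-08 to 0.00344. Its lost call thus did not hang on the size of the correlation alone. The adjusted permutation test of list means also gave 0 and 0. That test allows no p below 0.0286, so a list could pass only if many lists reached 0.0286 together. Its result therefore decides nothing here. The replicate numbers did not pair the samples (correlations of -0.021, -0.074 and -0.0017), and the fit with them as a replicate block, without saline 4, gave 1 gene higher, 2 lower, 6 lists higher and 5 lower. Signs turned only for genes that passed no test, and for 1 list. Leaving out libraries moved the log2 fold change of Cpt1a from -0.30 to 0.11 (turned without saline 4, and at 0.03 without PX-478 2), of Cyp7a1 from -0.17 (PX-478 3) to 0.50 (-0.01 without saline 1), of Ppara from -0.051 (saline 3) to 0.37 (-0.033 without PX-478 3), of Pgk1 from -0.25 to 0.10 (PX-478 1), of Acot3 from -0.089 (PX-478 1) to 2.32, of Apoe from -0.20 (PX-478 3) to 0.46 and of Clec4f from -0.47 to 0.033 (saline 4), and the block moved Cpt1a to 0.15 and Clec4f to 0.048. The adjusted p of the heat shock list ran from 0.000679 to 0.835, where it turned (saline 3). The causes were not tested. Other scalings, count filters and single columns kept the counts of genes called. Depth limits Psrc1, Eda2r, Mcm5 and Cdk1, which lie near the floor in saline.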

Other observations

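Several further lists fixed beforehand missed the threshold. The interferon response (17 of 26 higher, adjusted p = 0.303), antigen presentation (10 of 14 lower, 0.390), immediate early genes (11 of 18 lower, 0.390), NRF2 targets (13 of 18 lower, 0.109), xenobiotic metabolism (14 of 25 higher, 0.786), glucose production and glycogen (9 of 17 higher, 0.849) and periportal hepatocyte genes (10 of 14 higher, 0.0858) did not pass in camera. Their members with the smallest p were Irf1 at a log2 fold change of 0.64, H2-DMa at -0.75, Klf4 at -1.44, Srxn1 at -0.64, Gstm2 at -0.89, Gys2 at 0.78 and Etnppl at 0.80. Neutrophil, pancreas and skeletal muscle markers had 3, 3 and 2 tested genes, too few for the list test, and their means missed the threshold of the exact permutation test (adjusted p = 0.892, 0.892 and 0.943).

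A hypothesis written before its test was that the lower macrophage markers reflect fewer macrophages of every kind. The 8 genes assigned to lipid-associated macrophages (Trem2, Gpnmb, Cd9, Lgals3, Cd68, Lyz2, Mmp12 and Itgax) had a mean log2 fold change of -0.80 and separated the groups (exact permutation p = 0.0286, two-sided). Resident Kupffer cell genes (5, among them Clec4f and Timd4) had -0.46 (exact permutation p = 0.543). Both sets come from the macrophage list followed for its small p. The 8 include Lyz2, Lgals3, Cd68 and Gpnmb, lower when adjusted over that list alone, as was Vsig4 of the 5. The separation is therefore no independent support for the fall of that list. The difference between these sets did not itself separate the groups (exact permutation p = 0.400), so an equal fall of both and a fall confined to lipid-associated macrophages cannot be told apart with 7 libraries. Gpnmb, named after its values were seen, stood at 25.2 CPM in saline and 5.83 CPM in PX-478, and Clec4f at 117 and 104 CPM.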
